A study of Polypterus senegalus and Acipenser ruthenus and Danio rerio with 14 samples.

How the data were processed

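RNA was sequenced from scutes of the sterlet sturgeon (Acipenser ruthenus; labelled sizes 22, 26 and 68 mm), ganoid scales of the Senegal bichir (Polypterus senegalus; 60, 65 and 88 mm) and elasmoid scales of the zebrafish (Danio rerio; 30 mm), with 2 libraries per size, 14 in all. Per the labels' protocols, all animals were wild type, total RNA was extracted with a column kit (RNAqueous) and libraries followed Illumina's standard protocols. The labels give the size without saying how it was measured, and do not say whether the 2 replicates came from separate animals.

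The deposited tables, 1 per species, hold raw counts per gene, with no normalisation; every value is a whole number and column totals differ between libraries. Per the submitters' processing notes, featureCounts and DESeq2 were used and the only genome build named is GRCz11; no version or role is given. Per the file headers, each row carries the featureCounts columns for identifier, position, strand and length. In every row the length equals the span from start to end, so introns lie inside the counted interval and unspliced reads can enter a count. The aligner, the treatment of reads that map to several genes and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated, and genes with near-identical copies are uncertain. All count columns belong to the 14 samples, with 0 left over.

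The bichir table holds 11264 rows, all protein-coding, and each matches a gene and its coordinates in the gene table of assembly ASM1683550v1, which has 21953 protein-coding genes. The rest of the genes are missing from the table, so CPM (counts scaled to a common library total) are relative to the listed genes. The sturgeon table holds 46193 rows, of which 38705 carry only a locus number, 3556 are tRNAs and 3625 are named, with 3 symbols altered to dates; its assembly is not stated, so no sturgeon coordinates are given, and named genes are a small part of it. The zebrafish table holds 32520 rows with 20015 named, 3478 that repeat the symbol of an earlier row and 19 with a symbol altered to a date. Rows with 0 counts in every library numbered 267 in bichir, 7122 in sturgeon and 6435 in zebrafish.

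Depth is the column total of each table, from 22425788 to 44921620 counts. Computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Within a species, genes were kept by edgeR's filterByExpr, libraries were scaled by TMM, and each pair of sizes was tested with edgeR's quasi-likelihood F-test in a model with all 6 libraries, so that the 3 sizes share an estimate of the spread. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all tested genes, and the threshold was 0.05. A positive log2 change is higher in the larger fish. In camera and fry, log2 CPM used a prior count of 2. The muscle score, the correlations between replicates and the check of replicate numbers used log2(CPM + 1). The medians of cilium genes per library added less than 1 to CPM. The largest against the smallest size was the main comparison of bichir and of sturgeon. The zebrafish, with 1 size, was described only.

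The tests, the 20 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. For the main comparisons the rule named, among genes past the threshold with a symbol that is not only a locus number, at least 5 CPM in the higher group and no overlap between replicates, the 8 largest rises and 8 largest falls, plus up to 4 members per list with the smallest adjusted p, or, for a list with no call, up to 2 members with the highest counts. For neighbouring sizes and for the difference between species it named 4 rises and 4 falls. For the comparison of the 3 species it named the 10 genes with the highest CPM in each, and members of the bone, enamel, tooth and neural crest lists by rank. The lists were bone matrix and osteoblast, enamel and dentine matrix, tooth and placode signalling, neural crest, paraxial mesoderm and dermis, hox, osteoclast, cartilage, epidermis, pigment cell, Schwann cell and neuron, skeletal muscle, erythrocyte, leukocyte, endothelium and pericyte, cell cycle, immediate early and heat shock, nuclear oxidative phosphorylation, cytosolic ribosomal protein, and collagen processing and extracellular matrix. A gene joined a list where its symbol was a listed stem, alone or followed by a or b or by a copy suffix. That suffix rule also took sparcl1, hhipl1, rpl7l1 and rpl22l1, and some genes, such as ltk and dlx3, stand in more than 1 list. Lists with at least 5 tested members entered limma's camera with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a species; camera with a correlation estimated for each list and the directional test fry were alternatives. Calls "adjusted over the list alone" use the same edgeR p-values adjusted within a list. Genes named in the figures and the hypothesis lists of the closing section (motile cilia, interferon response) and the 16 muscle markers were chosen after values had been seen; bichir held 9 of these markers.

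Between species, counts of rows with the same symbol were summed. The difference between the size changes of bichir and sturgeon was tested as an interaction in edgeR over their 12 libraries and shared symbols, with CPM over those symbols only. Gene list ranks used the 2400 symbols shared by the 3 tables and detected in at least 1 library: each library's genes were turned into percentiles, the percentiles of a list's members were averaged, and species were compared by exact permutation tests over libraries, two-sided, with Benjamini-Hochberg adjustment over 27 tests. The smallest p such a test can give is 0.00216 between bichir and sturgeon and 0.0714 against the zebrafish. Spearman correlations between species are across genes and have no p-value.

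Alternatives tried were DESeq2's Wald test, RLE factors or library size alone in place of TMM, no low-count filter or one of 5 CPM in 2 libraries, the replicate number as a block, only the sizes compared, the largest size against the mean of the other two, each library left out in turn (a lone library of a size was then assumed to vary like the others), the copy of a symbol with the highest mean in place of the sum, only symbols with at least 1 CPM in every species, and only the smallest or largest size for ranks. A correction for the trend of log2 CPM with gene length, the muscle marker score as a covariate, and ranks over the 8376 symbols shared by bichir and zebrafish were added after the data had been seen. The length trend was fitted on counts scaled by library size alone, and TMM factors were then applied on top. A shift common to the genes of a library was thus taken out again, which moved the median of all genes. Counts up and down under that correction therefore do not measure gene length alone. In bichir the muscle score moved with size and little within a size, so its effect cannot be told apart from that of size. The steps were tested on simulated data with changed genes at known folds. Few genes were changed in each simulation, and every gene was drawn on its own from the fitted trend of the spread. The rates thus check the steps and do not give the power or the false calls of the real comparisons. For bichir 88 against 60 mm, 68.7%, 97% and 100% of genes changed by 2, 4 and 8-fold were called, with 8 calls among unchanged genes (10411 genes tested). For sturgeon 68 against 22 mm these were 1.5%, 53.7% and 97%, with 8 (32964 tested), and for the difference between bichir and sturgeon 19.4%, 80.6% and 95.5%, with 8 (2367 tested).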

Results

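RNA was sequenced in bulk from cells of the dermal armor of 3 fishes that carry different kinds of skin skeleton. These were the scutes (bony plates) of the sterlet sturgeon, the ganoid scales (thick bony scales with a hard mineralised coat) of the Senegal bichir, and the thin elasmoid scales of the zebrafish. The sturgeon was sampled at labelled sizes of 22, 26 and 68 mm, the bichir at 60, 65 and 88 mm and the zebrafish at 30 mm. There were 2 libraries per size and 14 in all. The series asks which genes the dermal armor of each species expresses, and its title ties that armor to trunk neural crest. Total counts for the bichir were 27754521 and 26726434 at 60 mm, 26364968 and 32405939 at 65 mm, and 22425788 and 22742176 at 88 mm. For the sturgeon they were 37239333 and 44477615 at 22 mm, 40094506 and 40073074 at 26 mm, and 43159175 and 42360283 at 68 mm. The zebrafish libraries held 39580697 and 44921620 counts. The bichir table lists 11264 of the 21953 protein-coding genes of assembly ASM1683550v1, so its totals are not full sequencing depths and unlisted genes were not analysed here. The Pearson correlation of log2 CPM between replicates, taken across genes, ran from 0.932 (sturgeon 26 mm) to 0.996 (zebrafish). Replicates differed by more than counting error in every group. The chi-square per degree of freedom, which is near 1 for counting error alone, ran from 17.3 (zebrafish) to 320 (sturgeon 26 mm). The labels do not say that replicates came from separate animals, so every p-value here measures only the spread between samples. Values are TMM-normalised CPM as mean ± SD with n = 2 libraries, unless another n is given. Adjusted p-values of single genes are Benjamini-Hochberg values from edgeR's quasi-likelihood test.

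Keratin transcripts of the epidermis were the most abundant in the zebrafish scale libraries. The keratin genes krt5 (53171 ± 6810 CPM, chromosome 23, 10173196 to 10177458 in GRCz11), krt91 (27670 ± 3930) and krt4 (8157 ± 1358) were among the 10 named genes with the highest counts. The others were mt-co1 (15965 ± 711), actb2 (10863 ± 257), eef1a1l1 (8750 ± 493), ptgdsb.1 (6272 ± 801), b2m (6147 ± 746), cd74a (5761 ± 520) and ahnak (5506 ± 260). Epidermal markers took 8.64% of the counts, cytosolic ribosomal proteins 6.23%, immediate early and heat shock genes 1.67% and leukocyte markers 1.14%. The leukocyte markers were led by the antigen-presentation chaperones cd74a and cd74b (2726 ± 374). Bone matrix and osteoblast genes took 0.191%, led by the type I collagen genes col1a1b (476 ± 72) and col1a2 (310 ± 37.4) and by sparc (231 ± 17.4). Enamel and dentine matrix genes took 0.0625%, among them fam83hb at 159 ± 2.23 CPM and itgb6 at 86.9 ± 2.35. The enamel matrix gene ambn (chromosome 1, 43926153 to 43933271) stood at 85.9 ± 15.8. Its neighbours scpp7 (43917934 to 43920576) and enam (43901966 to 43905263) stood at 64.1 ± 10.3 and 52.6 ± 13. Tooth and placode signalling genes took 0.0949%, with ctnnb1 at 332 ± 7.4 and dlx3b at 172 ± 15.2. Neural crest genes took 0.0941%, with tfap2c at 197 ± 6.75 and erbb3a at 89.8 ± 10.2. Oxidative phosphorylation genes took 0.387%, collagen processing and extracellular matrix genes 0.298%, cell cycle genes 0.125%, and osteoclast genes 0.0759% (ctsk at 287 ± 9.89). Skeletal muscle (0.0629%), erythrocyte (0.0485%), Schwann cell and neuron (0.0433%) and endothelium and pericyte (0.0429%) markers were rarer. The lowest shares were those of paraxial mesoderm and dermis (0.0379%), cartilage (0.0143%), pigment cell (0.0113%) and hox genes (0.00719%, with hoxb9a at 23 ± 2.04). With a single size, the zebrafish allows no comparison within the species.

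Bichir scales from 88 mm fish were compared with those from 60 mm fish to ask how expression in the ganoid scale differs between the smallest and the largest fish sampled. Transcripts of gsto2, a glutathione transferase, fell from 79.3 ± 6.82 to 6.03 ± 0.104 CPM (log2 change -3.72, SE 0.16, adjusted p = 0.000439). Those of socs2, which restrains cytokine and growth hormone signalling, fell from 36.2 ± 2.74 to 0.879 ± 0.547 (-5.37, SE 0.39, adjusted p = 0.00247). Transcripts of higd1a, a hypoxia-inducible mitochondrial protein, rose from 68 ± 21.5 to 532 ± 67.3 CPM (2.97, SE 0.25, adjusted p = 0.00337). The transcription factor zbtb16a rose from 3.77 ± 0.874 to 33.4 ± 11.5 (3.15, SE 0.32, adjusted p = 0.0075) and the transferrin receptor tfr2 from 0.832 ± 0.167 to 10.4 ± 0.755 (3.63, SE 0.32, adjusted p = 0.00412). The largest rises by fold were those of the proteasome subunit psmb12 (7.25, SE 1.12) and the ectonucleotidase entpd3 (5.31, SE 0.7). They were followed by the synaptic scaffold rims1b (5.15, SE 0.67) and the mitochondrial nucleotide kinase cmpk2 (4.09, SE 0.53). With the muscle marker score as a covariate, added later, psmb12 turned to -6.97 and did not pass. In bichir that score varied little within a size, so a turn of sign under it cannot be told apart from size. The cystine transporter slc7a11 rose by 2.92. After socs2, the largest fall was that of cfap52, a gene of motile cilia (-4.28, SE 0.8, adjusted p = 0.0296), whose counts differed between the 60 mm libraries themselves (15.8 ± 14.3 CPM). The guanylate cyclase subunit gucy1a1 (-3.73, adjusted p = 0.00825), the cilium gene mns1 (-3.66, adjusted p = 0.0423) and the immediate early gene fosab (-3.49, adjusted p = 0.0471) also fell. So did ttc6 (-3.04, adjusted p = 0.0496) and the fatty acid elongase elovl2 (-2.89, adjusted p = 0.0165). Under the muscle score covariate cfap52, mns1 and ttc6 turned to 1.83, 2.55 and 2.31, none past the threshold. In ASM1683550v1, gsto2 lies on chromosome 1 from 297355261 to 297373547 and socs2 on chromosome 8 from 70139946 to 70145699. There zbtb16a lies on chromosome 9 from 143784462 to 144035228 and psmb12 on chromosome 11 from 69049504 to 69058679.

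**Figure D1:**
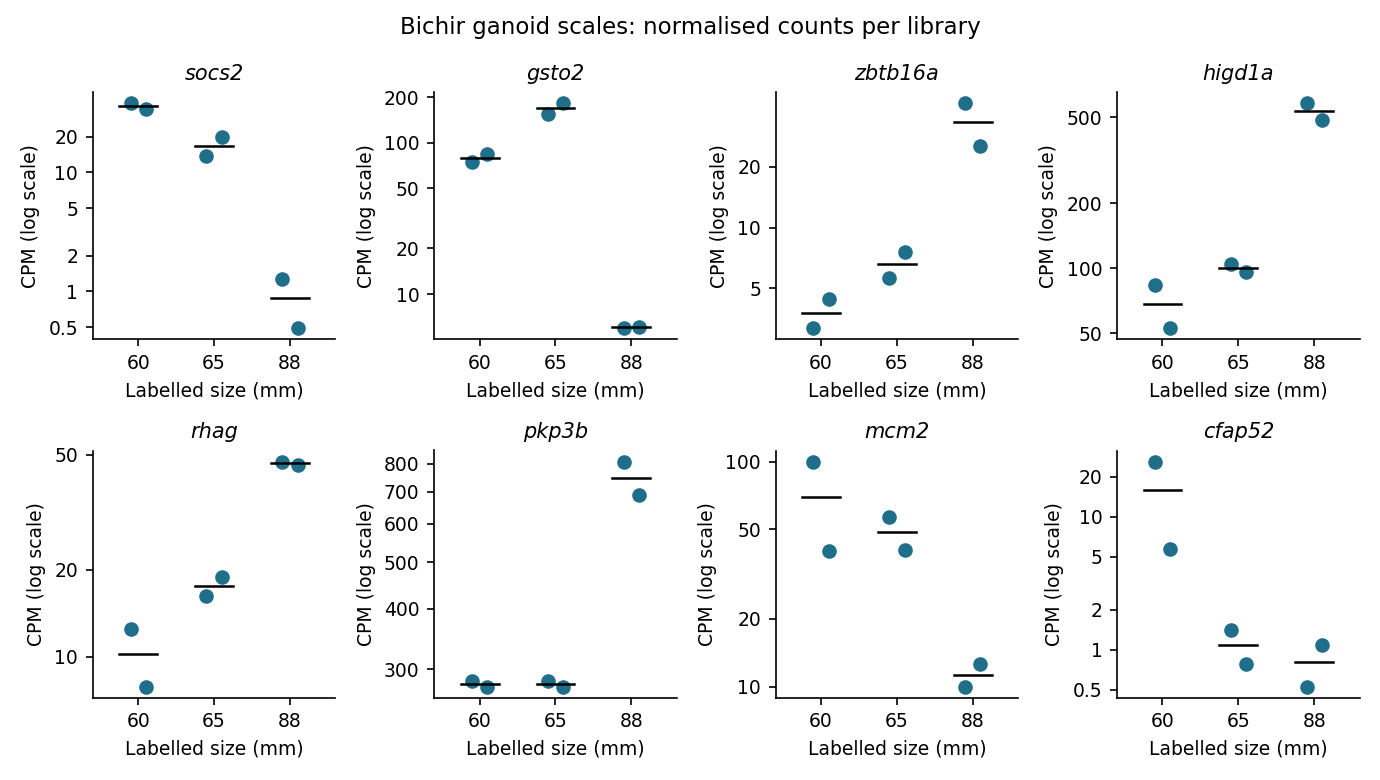
TMM-normalised CPM (log scale) of 8 genes in the 6 bichir scale libraries by labelled size in mm; each point is 1 library and each bar the mean of a size. Values of socs2 and gsto2 were lower in both 88 mm libraries than in the other 4, those of zbtb16a, higd1a, rhag and pkp3b were higher there, and cfap52 and mcm2 differed widely between the 60 mm libraries.

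Most genes of mineralised tissue did not pass the test between 60 and 88 mm. Of 20 bone matrix and osteoblast genes, wnt1 fell (-2.22, adjusted p = 0.032) and 19 did not pass, among them col1a2 (0.68, adjusted p = 0.5); 0 up and 1 down passed when adjusted over the list alone. None of the 5 enamel and dentine matrix genes passed over all genes (relt 0.55, fam20a 0.34), and 1 up and 1 down passed when adjusted over the list alone. Among 30 tooth and placode signalling genes, the hedgehog ligand shha (1.12 to 4.69 CPM, adjusted p = 0.0239) and fgf8a (0.133 to 0.814 CPM, adjusted p = 0.0393) rose. The Wnt target axin2 of that list fell (114 ± 18.7 to 49.3 ± 15.1 CPM, adjusted p = 0.0327), and 27 genes did not pass (4 up and 4 down adjusted over the list alone). Of 26 neural crest genes, mycn rose (127 ± 3.11 to 286 ± 16 CPM, adjusted p = 0.0136) and 23 did not pass. The glial receptor erbb3a (76.1 ± 3.8 to 28.5 ± 3.01, adjusted p = 0.0137) and the crest regulator sox10 (6.83 to 2.5, adjusted p = 0.0397) fell, with 2 up and 2 down adjusted over the list alone. Of 14 paraxial mesoderm and dermis genes only lum, a collagen-binding proteoglycan, rose (492 ± 235 to 1464 ± 213 CPM, adjusted p = 0.0434), as it did adjusted over the list alone (1 up). It turned to -1.02 with the muscle score as a covariate and did not pass. Among 25 genes of collagen processing and extracellular matrix, col12a1b (142 ± 54.4 to 460 ± 66 CPM) and tgfbi (122 ± 20.2 to 272 ± 32.2) rose, each at an adjusted p = 0.0221. The prolyl hydroxylase p4ha2 fell (32.2 to 14.5 CPM, adjusted p = 0.0301), with 3 up and 2 down adjusted over the list alone. In the osteoclast list of 9 the proton pump subunit tcirg1b fell (74.6 to 40.4 CPM, adjusted p = 0.0151; 2 down adjusted over the list alone). None of 23 hox genes (hoxa3a 0.67, hoxb3a -0.5) or 7 cartilage genes (col11a2 0.41, sox6 0.25) passed under either adjustment.

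None of these lists passed the set test, camera, with all libraries, but some did with a library left out. These were bone, hox and collagen processing without 60 mm replicate 2, neural crest and osteoclast without 60 mm replicate 1, collagen processing without 88 mm replicate 1 and osteoclast without 88 mm replicate 2. The bone list had a median log2 change of 0.09 (adjusted p = 0.669), the enamel list 0.55 (0.174), the tooth and placode list -0.18 (0.339) and the neural crest list -0.25 (0.147). Paraxial mesoderm genes had a median of 0.13 (0.28), hox genes 0.07 (0.28), osteoclast genes -0.28 (0.103) and collagen processing genes 0.19 (0.269). For cartilage the median was -0.08 while camera pointed up (adjusted p = 0.898), and for tooth and placode genes the directional test fry pointed up. Fry passed the enamel list up (adjusted p = 0.0477). The signs of these small medians hung on the scaling, since the median of all genes was -0.35 with library size alone and 0.3 with a correction for gene length. Camera ranks a list against the other genes. With library size alone it kept its direction for all 9 lists and passed hox genes up (adjusted p = 0.0466). With the gene-length correction it passed neural crest (adjusted p = 0.0351) and osteoclast (0.0496) genes down. Higher in both 88 mm libraries than in the other 4 and varying little within a size, the muscle marker score cannot be told apart from size. It was added later as a covariate. With it camera passed 7 of the 9 lists down: bone (median -2.45, adjusted p = 4.45e-08), hox (-2.38, 2.71e-07), tooth and placode (-1.05, 0.00416), collagen processing (-0.55, 0.00759), neural crest (-1.08, 0.00762), osteoclast (-1.25, 0.0256) and cartilage (-1.3, 0.0442). An estimated correlation was not tried under these settings.

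Of the lists of other cell types and of cell state, 6 passed camera between 60 and 88 mm, but 0 with an estimated correlation. All 26 cell cycle genes had negative log2 changes (median -0.64), and 6 fell under both adjustments, over all genes and adjusted over the list alone. They included the replication helicase subunits mcm2 (70.1 ± 42.7 to 11.3 ± 1.79 CPM, adjusted p = 0.0211), mcm6 (105 to 25.1, adjusted p = 0.0208), mcm4 (-2.23) and mcm5 (-2.49). The list ranked down in camera (adjusted p = 7e-06), a call lost at an adjusted p = 0.649 with an estimated correlation. It turned up with the muscle score as a covariate (median 0.74, camera adjusted p = 0.0442), and mcm2, mcm4, mcm5 and mcm6 had log2 changes of 0.88, 0.9, 1.43 and 0.6, none past the threshold. Nuclear genes of oxidative phosphorylation ranked up (median 0.36, camera adjusted p = 1e-06; adjusted p = 0.649 with an estimated correlation). Of 24, ndufb10 (61.8 to 110 CPM, adjusted p = 0.0187) and atp5f1d (0.75, adjusted p = 0.0219) rose, and 7 did adjusted over the list alone. Cytosolic ribosomal proteins ranked up (median 0.54, 68 of 69 positive, camera adjusted p = 6.81e-07; adjusted p = 0.675 with an estimated correlation). They turned down with the muscle score (median -1.43, camera adjusted p = 4.92e-09). Singly, 0 of the 69 passed in edgeR over all genes or adjusted over the list alone (rpl4 0.49, rps2 -0.07). Mitochondrial genes took 10.46% and 8.38% of the counts at 88 mm against 6.25% and 4.19% at 60 mm. Skeletal muscle markers ranked up (median 0.85, camera adjusted p = 0.000144; adjusted p = 0.649 with an estimated correlation). Of 17, mylpfa (0.363 to 4.7 CPM, adjusted p = 0.0129), tnnc1b (2.54), tnnt1 (2.71) and myl13 (1.5 to 5.29 CPM) rose, and the same 4 adjusted over the list alone. Their median was -0.52 with the score of muscle markers in the model (camera adjusted p = 0.883). That score is itself built from muscle markers, so this fit cannot test their rise. The muscle marker score, a mean log2(CPM + 1), was 1.63 and 1.65 at 88 mm against 1.09 and 1.25 at 60 mm.

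Erythrocyte genes ranked up at 88 mm (median 0.99, camera adjusted p = 0.00106; adjusted p = 0.649 with an estimated correlation). The membrane channel rhag (10.2 ± 3.27 to 46.8 ± 0.755 CPM, adjusted p = 0.00786) and the spectrin sptb (8.69 ± 1.83 to 28.2 ± 3.71, adjusted p = 0.0171) rose among 6, and 4 rose adjusted over the list alone. Leukocyte genes ranked down (median -0.57, camera adjusted p = 0.00179; adjusted p = 0.649 with an estimated correlation). Of 16, the T cell kinase lck (42.1 to 21.7 CPM, adjusted p = 0.0239) and coro1a (181 to 104, adjusted p = 0.0458) fell, with 1 up and 8 down adjusted over the list alone. The 6 lists that passed kept their sign with library size alone, where oxidative phosphorylation had a median of 0.03 and cell cycle of -0.97, and with the gene-length correction. The cell cycle, ribosomal and skeletal muscle lists turned with the muscle score as a covariate, which cannot be told apart from size here. For the skeletal muscle list that turn tests nothing, since the score is built from muscle markers. Immediate early and heat shock genes were split: cebpb rose (1.13, adjusted p = 0.00825) and 5 of 23 fell. Among the falls were nr4a1 (125 to 40.5 CPM, adjusted p = 0.00337), egr1 (227 to 52.7, adjusted p = 0.0136) and dusp1 (-1.03, adjusted p = 0.0165). The list had 2 up and 5 down adjusted over the list alone and a median of -0.4 (camera adjusted p = 0.165), and fry passed it down (adjusted p = 0.0477). In the epidermis list of 11, the plakophilin pkp3b (279 ± 4.63 to 747 ± 84.4 CPM, adjusted p = 0.00825) and the splicing factor esrp1 (381 ± 11.4 to 684 ± 111, adjusted p = 0.0389) rose under both adjustments. Its median was 0.26 (camera adjusted p = 0.103) but -0.07 with library size alone. No member of the other lists passed under either adjustment. These were 18 pigment cell genes (median -0.52, camera adjusted p = 0.0573; kita 0.24, slc24a5 0.21) and 14 Schwann cell and neuron genes (-0.42, 0.174; fabp7b 0.1, ncam1a -0.4). The last were 12 endothelium and pericyte genes (-0.58, 0.147; notch3 0.45, sox7 -1.09).

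Between 60 and 88 mm, 711 of 10453 tested bichir genes passed, 385 up and 326 down. Library size alone gave 138 up and 740 down with the median of all genes at -0.35. The gene-length correction, added later, gave 1275 up and 180 down with that median at 0.3. That setting applies TMM on top of a trend that already held the shift between libraries, so the split does not measure gene length alone. With the muscle score as a covariate 510 genes passed, of which 63 were among the 711. The count rested on both 88 mm libraries, with 4 genes without replicate 1 and 34 without replicate 2, and DESeq2 called 1596 on all libraries. Both socs2 (-4.83 to -6.19) and gsto2 (-3.63 to -3.78) stayed past the threshold without any of the 6 libraries. Camera passed 6 of the 20 lists, but 11 without 60 mm replicate 1, with neural crest, osteoclast, pigment cell, Schwann cell and endothelium lists added. It passed 12 with the gene-length correction, and the leukocyte list was not among the 8 that passed without 60 mm replicate 2. With the filter of 5 CPM in 2 libraries the osteoclast list was added (adjusted p = 0.0472), and the skeletal muscle list, with 1 gene left, was not tested.

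Of the neighbouring bichir sizes, 65 and 88 mm gave calls on single genes. Transcripts of gsto2 fell from 168 ± 18.7 to 6.03 ± 0.104 CPM (-4.8, adjusted p = 0.000118) and those of socs2 fell too (-4.25, adjusted p = 0.00572). The amine-synthesis enzyme ddc fell from 100 ± 74.8 to 10.7 ± 3.65 CPM (-3.24, adjusted p = 0.0242). The transcription factor klf4, which acts in epithelial barriers, fell from 906 ± 442 to 154 ± 13.7 CPM (-2.56, adjusted p = 0.0346). Transcripts of psmb12 (7.16, adjusted p = 0.0221), rims1b (4.06), entpd3 (3.58, adjusted p = 0.0273) and tfr2 (3.28, adjusted p = 0.00624) rose. In all 294 genes rose and 237 fell. The split was 88 and 393 with library size alone, where the median of all genes was -0.31. With the gene-length correction, where TMM came on top of the length trend, it was 897 and 110, with that median at 0.28. With the muscle score 827 passed, of which 130 were among the 531. The count of 531 became 3 and 6 without 88 mm replicate 1 and 2, and 87 and 64 without 65 mm replicate 1 and 2. It became 1087 and 1098 without 60 mm replicate 1 and 2. Between 60 and 65 mm edgeR called 0 genes (464 at an unadjusted p under 0.05) and DESeq2 73. There edgeR called 55 without 60 mm replicate 2 and 1 without 65 mm replicate 1.

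Sturgeon scutes from 68 mm fish were compared with those from 22 mm fish to ask the same question of the scute, over a wider range of size. The cartilage collagen gene col9a1b fell from 14 ± 4.04 to 0.141 ± 0.021 CPM (log2 change -6.6, SE 0.46, adjusted p = 0.0133). The chondrocyte transcription factor sox6 fell from 16.5 ± 5.22 to 1.41 CPM (-3.55, SE 0.36, adjusted p = 0.0135), and the proteoglycan epyc from 13.3 ± 2.33 to 1.09 (-3.6, SE 0.55, adjusted p = 0.0204). The ligand shha fell from 8.43 ± 5.23 to 0.0592 ± 0.054 CPM (-7.06, SE 1.04, adjusted p = 0.0194). Its receptor and target gene ptch2 fell from 10.8 ± 3.73 to 0.649 (-4.05, SE 0.39, adjusted p = 0.0135). The muscle marker score fell along with them, from 6.88 and 7.79 at 22 mm to 1.59 and 4.96 at 68 mm. The transcription factors osr1 (0.654 ± 0.04 to 11.6 ± 0.699 CPM, adjusted p = 0.0133) and emx2 (2.97 ± 1.22 to 32.4 ± 0.835, adjusted p = 0.0218) rose by 4.14 (SE 0.37) and 3.44 (SE 0.55). Transcripts of the NADPH oxidase nox1 rose from 1.74 ± 0.518 to 23.9 ± 4.01 CPM (3.78, adjusted p = 0.0133), and those of the secreted mucin muc5e from 13.5 ± 7.79 to 141 ± 17.6 (3.39, adjusted p = 0.0219). The microfibril gene mfap5 rose from 2.96 ± 0.818 to 27.5 ± 4.38 CPM (3.21, adjusted p = 0.0218), with vwa5b2 (3.28), the leukotriene receptor ltb4r2b (3.14) and the Polycomb gene pcgf6 (2.8). The largest falls also held ankrd1a, an ankyrin repeat protein of muscle (-7.65, SE 1.87, adjusted p = 0.0456), and ckbb, a creatine kinase (-7.38, SE 1.83, adjusted p = 0.0473). Both varied widely at 22 mm (111 ± 94 and 34.3 ± 46 CPM). The nuclear receptor nr4a3 (-5.69), the anion exchanger slc4a1b (-5.1), myoc (-4.89) and the co-chaperone bag2 (-4.76) completed the 8 largest falls.

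**Figure D2:**
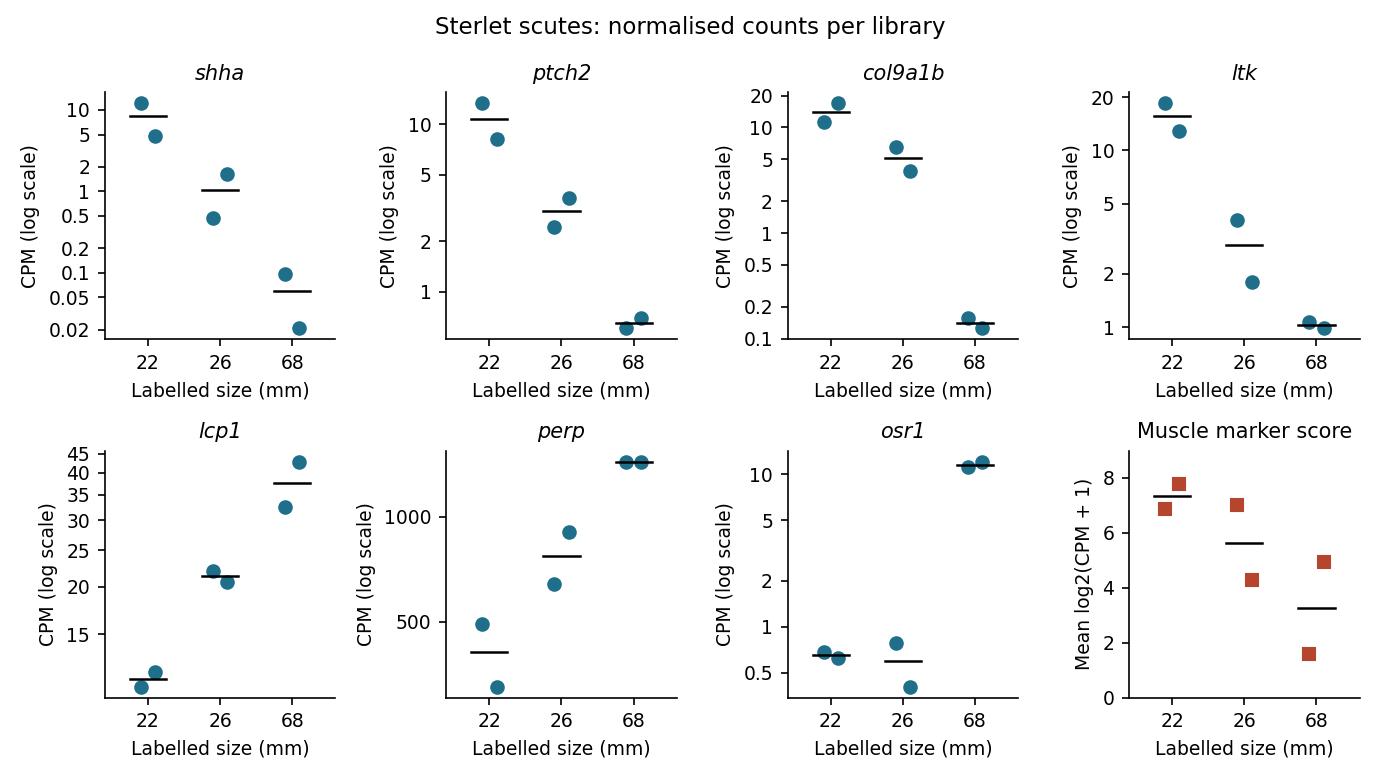
TMM-normalised CPM (log scale) of 7 genes in the 6 sturgeon scute libraries by labelled size in mm, and, in the last panel, the muscle marker score of each library (mean log2(CPM + 1) over 16 markers); each point is 1 library and each bar the mean of a size. Values of shha, ptch2, col9a1b and ltk were lower and those of lcp1, perp and osr1 higher in both 68 mm libraries than in both 22 mm libraries, while the muscle score was 6.88 and 7.79 at 22 mm and 1.59 and 4.96 at 68 mm.

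Camera passed 7 sturgeon lists: cartilage, pigment cell, tooth signalling, leukocyte, collagen processing, paraxial mesoderm and cytosolic ribosomal genes. The muscle marker score, 6.88 and 7.79 at 22 mm, 7 and 4.27 at 26 mm and 1.59 and 4.96 at 68 mm, was lower at the larger size as the falling lists were. Of 6 cartilage genes 3 fell (col9a1b, sox6, epyc), and the same number adjusted over the list alone. None of the 6 had a positive change (median -2.34, camera adjusted p = 0.0129; adjusted p = 0.501 with an estimated correlation). Among 10 pigment cell genes the receptor ltk (15.7 ± 3.92 to 1.03 CPM, adjusted p = 0.0155), bco1 (-2.48, adjusted p = 0.0309) and mitfb (-2.09, adjusted p = 0.0395) fell. The purine enzyme xdh of that list rose (8.15 to 31.4 CPM, adjusted p = 0.0218), with 1 up and 8 down adjusted over the list alone. Pigment cell genes ranked down in camera (median -2.44, adjusted p = 0.0129; adjusted p = 0.508 with an estimated correlation). Of 11 tooth and placode genes shha, ptch2 and the Wnt antagonist dkk1b (-3.04, adjusted p = 0.0446) fell, 0 rose, and 4 fell adjusted over the list alone. That list also ranked down (median -0.89, camera adjusted p = 0.0129; adjusted p = 0.599 with an estimated correlation). Leukocyte genes ranked up (median 1.4, camera adjusted p = 0.0209; adjusted p = 0.501 with an estimated correlation). Of 10, 6 rose, including the actin bundler lcp1 (11.4 ± 0.727 to 37.6 ± 7.28 CPM) and the pan-leukocyte phosphatase ptprc (3.37 ± 0.42 to 14.4 ± 1.79), at an adjusted p = 0.0154 and 0.0176. Also among the 6 were arhgdig (88.1 ± 18.8 to 290 ± 5.74 CPM) and il34 (1.63). The scavenger receptor marco fell (-2.68, adjusted p = 0.0246), and 7 up and 2 down passed when adjusted over the list alone.

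Collagen processing and extracellular matrix genes ranked down in the sturgeon (median -0.97, camera adjusted p = 0.0247; adjusted p = 0.508 with an estimated correlation). The prolyl hydroxylase p3h1 was the single call of 11, also adjusted over the list alone (61.8 ± 17.7 to 24 ± 3.91 CPM, adjusted p = 0.03). Paraxial mesoderm and dermis genes ranked down (median -0.85, camera adjusted p = 0.0428; adjusted p = 0.501 with an estimated correlation). Of these the dermal proteoglycan dcn fell (273 ± 0.827 to 141 ± 16.8 CPM, adjusted p = 0.0497), 7 did not pass, and 0 passed in edgeR adjusted over the list alone. Cytosolic ribosomal proteins ranked down (median -0.45, camera adjusted p = 0.0256; adjusted p = 0.737 with an estimated correlation) but had a median of 0 with library size alone. Singly, 0 of 20 passed in edgeR under either adjustment (rpl18 -0.64, rpl36a -0.37). Of 8 neural crest genes the transcription factor prdm1b rose (10.2 to 30.9 CPM, adjusted p = 0.0252), ltk fell and 6 did not pass (1 up and 2 down adjusted over the list alone). Their median was -0.16 (camera adjusted p = 0.71) but 0.31 with library size alone. Of 6 osteoclast genes snx10b rose under both adjustments (1.3, adjusted p = 0.0349). Their median was 0.43 (camera adjusted p = 0.229) but -0.11 with the gene-length correction. None of 6 hox genes passed under either adjustment (hoxb9a -2.4, hoxb7a -1.39; median -1.89, camera adjusted p = 0.229). Nor did any of 14 cell cycle genes (hmgb2a 0.53, top2a 0.41), whose median was 0.17 (camera adjusted p = 0.387) but -0.28 with the gene-length correction.

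In sturgeon lists with fewer than 5 tested genes, the epidermal gene perp, which acts in desmosomes, rose (409 ± 117 to 1432 ± 5.27 CPM, adjusted p = 0.0346). The glial receptor gfra1a (-2.17, adjusted p = 0.0389), slc4a1b of the erythrocyte list and the pericyte channel gene abcc9 (-3.56, adjusted p = 0.0481) fell. None of 3 bone matrix genes passed, although col1a2 stood at 1933 ± 680 CPM at 68 mm and 7135 ± 59.8 at 22 mm (-1.88, adjusted p = 0.08; col5a2b -0.76). Neither did the enamel list's itgb6 (0.37) nor the muscle list's tnnc1b (-1.59, 282 ± 368 against 851 ± 255 CPM). The 4 immediate early and heat shock genes (hspa5 0.7, cebpd -0.03) and the 4 oxidative phosphorylation genes (atp5pd -1.52, ndufs1 -1.44) did not pass over all genes. Adjusted over the list alone, 1 epidermis gene passed up. Down passed 3 Schwann cell and neuron, 1 erythrocyte, 1 endothelium and pericyte and 4 oxidative phosphorylation genes. No bone, enamel, muscle or immediate early gene did.

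Between 22 and 68 mm, 6038 of 33376 tested sturgeon genes passed, 3258 up and 2780 down. Library size alone gave 3740 up and 1519 down with the median of all genes at 0.42. The gene-length correction gave 1126 up and 2848 down with that median at -0.51. The latter split holds TMM applied on top of the length trend and does not measure gene length alone. The calls rested on both 68 mm libraries and on 22 mm replicate 2. Without 22 mm replicate 2 edgeR called 0 genes (9132 at an unadjusted p under 0.05), without 68 mm replicate 1 it called 0 (6635) and without 68 mm replicate 2 it called 0 (8055). With the muscle score as a covariate, added later, edgeR called 0 (4521). DESeq2's Wald test, without the score, called 10849. With the score camera kept the tooth, cartilage, pigment cell, leukocyte and collagen processing calls. It lost the paraxial (adjusted p = 0.119) and ribosomal (0.761) calls, and the hox median went from -1.89 to 0.47. The replicate number as a block left 454 genes. Of the 7 lists that passed camera, cartilage and pigment cell lists passed without any library. With the filter of 5 CPM in 2 libraries the pigment cell list did not pass (6 genes, median -2.5, camera adjusted p = 0.0577), and the cartilage list, with 3 genes left, was not tested. Tooth, leukocyte, collagen processing, paraxial and ribosomal lists were not among the 3 that passed without 22 mm replicate 1. The last 3 of these were not among the 4 that passed without 68 mm replicate 2. The paraxial and ribosomal lists were not among the 5 without 22 mm replicate 2, nor the ribosomal list without 68 mm replicate 1. Library size alone moved the leukocyte, paraxial and ribosomal medians to 1.85, -0.4 and 0. It ended their calls (camera adjusted p = 0.06, 0.0637 and 0.176 in that order). The gene-length correction ended those of the paraxial and pigment cell (both 0.0747) and the cartilage, ribosomal and collagen processing lists (each 0.0557). Their medians moved down with the median of all genes, to -1.42, -3.04, -2.84, -0.95 and -1.22 in that order. Sturgeons are partly tetraploid, so near-identical copies of a gene may share reads.

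Between 26 and 68 mm in the sturgeon, osr1 (4.3, adjusted p = 0.0301), vwa5b2 (4.11, adjusted p = 0.0329), pcgf6 (3.24, adjusted p = 0.0284) and ltb4r2b (2.74, adjusted p = 0.0455) rose. Falls were led by nr4a3 (-5.91, adjusted p = 0.0451) and col9a1b (-5.16, adjusted p = 0.0301). The matricellular gene ccn2a (-2.73, adjusted p = 0.0425) and the peptide-processing enzyme cpe (-2.67, adjusted p = 0.0451) followed. In all 287 genes rose and 344 fell. The split was 218 and 160 with library size alone (median of all genes 0.12). It was 86 and 352 with the gene-length correction, where TMM came on top of the length trend (median -0.23). The count of 631 became 0 in edgeR with the replicate number as a block (6413 at an unadjusted p under 0.05), 4 when only these sizes were fitted and 199 with the muscle score. It became 0 in edgeR without 68 mm replicate 1 or 2 (3417 and 4483 at an unadjusted p under 0.05), against 4628 with DESeq2 on all libraries. It became 4 without 22 mm replicate 1 or 2, 210 without 26 mm replicate 1 and 10 without 26 mm replicate 2. Between 22 and 26 mm edgeR called 0 genes (6459 at an unadjusted p under 0.05), DESeq2 called 2779, and edgeR called 301 without 22 mm replicate 1. Library size alone and the gene-length correction moved the median of all genes there to 0.25 and -0.31.

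Bichir and sturgeon were then compared for their change with size (88 against 60 mm and 68 against 22 mm). Constant differences of species, gene length and annotation drop out of this test, although the size ranges need not be the same stage. The hedgehog ligand shha differed in sign: its log2 change was 2.07 in bichir and -7.03 in sturgeon, a difference of 9.09 (SE 1.07, adjusted p = 0.00137). Differences in the same direction were found for amdhd1, an enzyme of histidine breakdown (7.33, SE 1.01, adjusted p = 0.0024), and allc, an enzyme of purine breakdown (8.14, SE 2.1, adjusted p = 0.0244). The homeobox gene eve1 also differed (7.76, SE 1.71, adjusted p = 0.0153), and is listed at 0 in both 68 mm sturgeon libraries. In the other direction were the motile cilium genes rsph3 (-4.94, SE 1.47, adjusted p = 0.0391), cfap58 (-4.91, SE 1.44, adjusted p = 0.0383) and cfap300 (-4.54, SE 1.05, adjusted p = 0.0158). So was the homeobox gene tlx1 (-10.76, SE 3.33, adjusted p = 0.0488), which is listed at 0 in both 22 mm sturgeon libraries. The fitted values of eve1 and tlx1 depend on the prior count and are no bounds. Leukocyte genes had median changes of opposite sign, -0.58 in bichir and 1.77 in sturgeon over 5 shared genes. Their difference was -2.08 (camera adjusted p = 0.000185; adjusted p = 0.143 with an estimated correlation). Cytosolic ribosomal protein genes (18 genes, 0.91, camera adjusted p = 0.00968) and collagen processing genes (6 genes, 1.5, camera adjusted p = 0.0343) also differed, each at an adjusted p = 0.502 with an estimated correlation. The muscle marker score was higher at the larger size in bichir and lower in sturgeon. With that score as a covariate in each species, added later, the leukocyte difference was -3.36 (camera adjusted p = 0.000156). The ribosomal difference turned to -1.54 (camera adjusted p = 9.51e-06), and that of collagen processing to -0.16 (0.84). In that fit rsph3, cfap58 and tlx1 turned to 3.9, 3.42 and 2.27 and did not pass, while shha kept its sign and passed. Without the score, the tooth and placode (1.07, camera adjusted p = 0.0543), paraxial mesoderm (1.49, 0.0543), pigment cell (2.64, 0.0575) and cell cycle (-0.71, 0.0575) lists did not pass. Nor did the hox (2.18, 0.26) and neural crest (0.71, 0.316) lists.

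In the test without the score 539 of 2376 shared genes passed, 251 with the higher change in bichir and 288 with the higher change in sturgeon, against 6 with the score. The changes of the species had a Spearman rho of -0.03 across genes, which are not replicates. Among shared genes, 10 were called higher in the larger fish of both species, among them the glutathione reductase gsr and ltb4r2b, where independent lists would share 6.15 (two-sided Fisher exact p = 0.114). Called lower in both were 2, ism1 and stk17al, where 5.25 would be shared (two-sided Fisher exact p = 0.146). Another 18 were called in both species in opposite directions. The count of 539 became 308 without bichir 60 mm replicate 1, and 235 and 258 without bichir 88 mm replicate 1 and 2. It became 274 without sturgeon 22 mm replicate 2, and 206 and 328 without sturgeon 68 mm replicate 1 and 2.

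Last, the standing of each gene list within a library was compared between the 3 species, by the mean expression percentile of its members among the 2400 symbols shared by all tables. Tooth and placode signalling genes stood higher in bichir scales than in sturgeon scutes. Their mean percentile was 46.2 ± 2.2 in bichir (SD, n = 6), 28.2 ± 5.5 in sturgeon (n = 6) and 21.9 ± 0.6 in zebrafish (n = 2). Every bichir library lay above every sturgeon library (two-sided exact permutation p = 0.00216, the smallest possible, adjusted p = 0.0292 over 27 tests). The BMP and Wnt antagonist sostdc1a stood at percentile 87 in bichir, 1.4 in sturgeon and 2.1 in zebrafish, and the growth factor bmp2a at 84.6, 33.3 and 2.1. The 2.1 of both genes in zebrafish is a tied rank at the floor, and 1.4 in sturgeon lies there too. In a list of 10 genes sostdc1a thus makes a large part of the gap between bichir and sturgeon. A sturgeon copy under a locus number would be missed. Paraxial mesoderm and dermis genes stood lower in bichir (36.1 ± 1.4) than in sturgeon (44.1 ± 4.4; two-sided exact permutation p = 0.00216, adjusted p = 0.0292), with 36 in the zebrafish. Neural crest genes stood at 52.6, 53.6 and 63.1 in bichir, sturgeon and zebrafish. Among them id3 stood at 93, 86.2 and 88.5, mycn at 95.4, 77.9 and 59.7, and ltk at 34.6, 33.6 and 77. Cell cycle genes stood at 54.2, 63.1 and 45.9 and collagen processing genes at 88.4, 80.8 and 58.1. Between bichir and sturgeon their two-sided exact permutation p of 0.0195 and 0.0346 gave an adjusted p of 0.113. Leukocyte genes stood at 75.4, 68.4 and 93.1 and ribosomal proteins at 97.3, 96.3 and 87.4. Pigment cell genes stood at 21.4, 27.4 and 22.6, and hox genes at 21.4, 24.2 and 19.1. Tests against the zebrafish could not go below an exact p of 0.0714 and none passed. Of bone genes, col1a2 stood at percentile 100 in bichir and sturgeon and 98.6 in zebrafish, and sost, an osteocyte gene, at 36.3, 69.3 and 51.1. The enamel list's itgb6 stood at 45.2, 80.4 and 93.1.

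**Figure D3:**
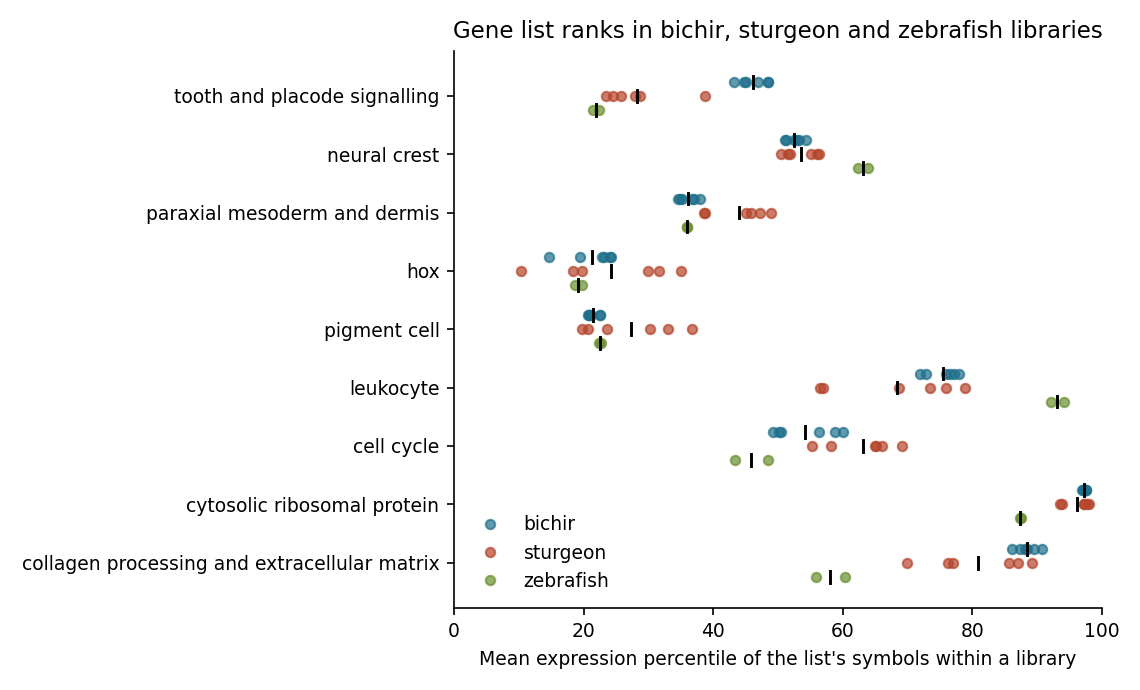
Mean expression percentile, within each library and among 2400 shared symbols, of the members of 9 gene lists in 6 bichir, 6 sturgeon and 2 zebrafish libraries; each point is 1 library and each bar a species mean. Tooth and placode genes lay between 43.2 and 48.5 in the bichir libraries and between 23.5 and 38.7 in the sturgeon libraries.

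The type I collagen gene col1a2 was the highest nuclear gene among the 10 named genes with the most counts in both bichir and sturgeon, where krt5 headed the zebrafish list. In bichir (n = 6) these genes were col1a2 (26878 ± 10778 CPM), COX1 (23509 ± 11207), eef2b (14695 ± 2686), COX3 (13163), COX2 (8800), rps2 (7196), vim (7070), CYTB (6105), rpl4 (5937) and rplp0 (5780). In sturgeon (n = 6) they were COX1 (6930 ± 2406), COX2 (5574), col1a2 (5442 ± 3289), COX3 (4255), actb1 (2789), CYTB (1724), rps27.2 (1246), rpl18 (1215), ATP6 (1164) and ND5 (1086). Across shared genes, mean expression had a Spearman rho of 0.678 between bichir and sturgeon, 0.683 between bichir and zebrafish and 0.621 between sturgeon and zebrafish. Species cannot be told apart here from genome, annotation and fish size. Both calls on list ranks were lost in the exact permutation test, with 0 lists past the threshold, when only symbols with at least 1 CPM in every species were used. The tooth and placode list then stood 8.2 percentiles higher in bichir (7 genes, two-sided exact permutation p = 0.0281) and the paraxial list 7.4 lower (5 genes, p = 0.0368), each at an adjusted p = 0.101. With only the smallest or only the largest size no such test could pass (2 against 2 libraries, smallest p 0.333). There the differences were 12.2 and 22.7 for tooth and placode genes and -10.8 and -2.4 for paraxial genes.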

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

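Of the tests in this part, those on cartilage and epidermis, that of the falls relative to all genes and that of the cilium genes with the muscle score were chosen only after the result was seen, and the gene-length correction and the muscle score were added after the data had been seen. The results here were picked out because the change with size differed between bichir and sturgeon in a direct test of that difference (edgeR or camera, Benjamini-Hochberg). The sturgeon falls are the exception, and come from the test within sturgeon.

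The motile cilium genes rsph3 (-4.94), cfap58 (-4.91) and cfap300 (-4.54) had lower log2 changes in bichir than in sturgeon, and 35 of 36 other motile cilium genes tested in bichir, none of which had been looked at before, were lower at 88 than at 60 mm (median -2.32, quartiles -3.14 to -1.15). The fall leans on a single library. The median log2 CPM of these genes was 4.29 in 60 mm replicate 1, 2.23 in replicate 2, and 1.08 and 1.75 at 88 mm. The master regulator of motile cilia, foxj1a, stood at 20.9 and 1.16 CPM at 60 mm, 0.935 and 0.217 at 65 mm and 0.105 and 0.886 at 88 mm. It was thus already low at 65 mm, as was tekt4 (2.47 and 0.0621 CPM, against 1.42 and 2.41 at 88 mm). Without 60 mm replicate 1 the median was -0.75 (quartiles -1.14 to -0.08), and without replicate 2 it was -3.07, so a fall of the whole gene set and a single library rich in ciliated cells both stay open and cannot be told apart with 2 libraries (fry adjusted p = 0.196; camera p = 9.5e-09, or 0.271 with an estimated correlation). A smaller share of epidermis at 88 mm is argued against as the cause of a fall of this size. The epidermis list had a median of 0.26 (quartiles -0.1 to 0.66, or -0.07 with library size alone). It took 0.528% and 0.413% of the counts at 60 mm and 0.487% and 0.445% at 88 mm. The highest share was in 60 mm replicate 1, where the cilium genes were highest too. With the muscle score as a covariate the median of the 36 genes was 3.64 (quartiles 2.25 to 4.58), while their median SE grew from 0.71 to 1.2. That fit cannot settle the direction. The score was 1.09 and 1.25 at 60 mm, 1.24 and 1.33 at 65 mm and 1.63 and 1.65 at 88 mm. Its slope thus stretches small gaps within a size, as between the 60 mm libraries, over the size difference. With the score of each species as a covariate, rsph3 and cfap58 turned to 3.9 and 3.42 in the difference between species.

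Within sturgeon, 2780 of 33376 genes fell from 22 to 68 mm, with a median log2 change of -1.84 (quartiles -2.71 to -1.29). More muscle RNA in the smaller fish might explain this, as muscle markers had a median change of -3.49, and 71% of the falling genes rose with the muscle score between libraries against 48.5% of all genes. The 16 markers were chosen after values had been seen, so their fall is no independent evidence. The planned muscle list held 1 tested sturgeon gene, tnnc1b (-1.59, edgeR adjusted p = 0.461), which did not pass. With the score in the model the median of the falling genes was -1.47 (quartiles -2.22 to -0.99), while 0 genes passed in edgeR. That cannot decide whether muscle RNA is the whole cause. The falling genes were called by a test that favours little spread within a size, and the slope of the score rests on that spread. The change shrank, the median SE grew from 0.34 to 0.53 and the residual degrees of freedom fell from 3 to 2, and which of these ended the calls was not tested apart (1449 of the 2780 kept an unadjusted p under 0.05). A trend with gene length is argued against as the whole cause. With the trend removed, 76.3% of the falling genes stayed past the threshold, short of the 4 in 5 set beforehand. TMM came on top of the trend in that fit and the median of all genes was -0.51, so this percentage cannot be read by itself. Relative to all genes, though, the median change of the falling genes was -1.81 (upper quartile -1.26), against -1.82 with the trend kept. Why the rest lost their call was not tested. A smaller share of cartilage stays open (median of the cartilage list -2.34, quartiles -3.59 to -0.95), which cannot be told apart from a change within cells because it moves with size.

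In all, 539 of 2376 shared genes had size changes that differed between the species, and 6 with the muscle score as a covariate in each. None of the 3 list differences passed with an estimated correlation (adjusted p = 0.143 for leukocyte and 0.502 for the other two). The leukocyte list differed by a median of -2.08, with 5 shared genes lower at the larger size in bichir and higher in sturgeon by their medians (-0.58 and 1.77). The cytosolic ribosomal protein list differed by 0.91 (0.34 in bichir and -0.4 in sturgeon), but by -1.54 with the score (-1.65 and 0.01). The collagen processing and extracellular matrix list differed by 1.5 (0.27 and -1.01), but by -0.16 with the score (-1.34 and -0.97). The hedgehog ligand shha differed by 9.09 (2.07 and -7.03). The purine enzyme allc differed by 8.14 (0.08 and -8.06). The histidine enzyme amdhd1 differed by 7.33 (1.16 and -6.17). The homeobox gene eve1 differed by 7.76 in the fit (2.24 and -5.52), and is listed at 0 in both sturgeon libraries of 68 mm. The homeobox gene tlx1 differed by -10.76 in the fit (-3.45 and 7.31), and is listed at 0 in both sturgeon libraries of 22 mm, so that neither fitted value is a bound.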

How the results depend on the processing

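The gene-length correction, the muscle score covariate and the ranks over symbols of bichir and zebrafish only were chosen after seeing the data; the other alternatives were planned. Where no reason is given below, the cause was not tested. In bichir the muscle score moved with size and little within a size, so turns of sign with it cannot be told apart from size. The score is built from muscle markers, so turns of skeletal muscle genes with it test nothing. Over all alternatives the named genes kept their label 792 times for bichir 88 against 60 mm (176 lost and 5 gained a call, 10 reversed). They kept it 99 times for 88 against 65 mm (20 lost, 1 reversed) and 555 times for sturgeon 68 against 22 mm (205 lost, 20 gained). For sturgeon 68 against 26 mm it was 53 times (67 lost), and for the difference between species 99 times (48 lost, 3 reversed). Reversals were counted only for genes with a call in the main fit, where they were rarer than lost calls. A gene without a call that changed sign counts as kept, as rps2 of bichir did (-0.35 to 0.29 with a library left out). DESeq2 called more genes than edgeR: 1596, 73 and 1323 for bichir 88 against 60, 65 against 60 and 88 against 65 mm, and 10849, 2779 and 4628 for sturgeon 68 against 22, 26 against 22 and 68 against 26 mm. The gene-length correction gave 1455, 1007 and 3974 for bichir 88 against 60, bichir 88 against 65 and sturgeon 68 against 22 mm, and 12 bichir lists. These counts of genes hold TMM applied on top of the length trend. With the muscle score the counts were 510 (bichir 88 against 60 mm, of which 63 were among the 711 called without it), 827 (bichir 88 against 65 mm, of which 130 were among the 531), 0 (sturgeon 68 against 22 mm, where edgeR had 4521 at an unadjusted p under 0.05 and a degree of freedom is spent on the score), 199 (sturgeon 68 against 26 mm) and 6 (difference between species, where tlx1, rsph3 and cfap58 reversed to 2.27, 3.9 and 3.42). In bichir, whose score rises with size, it reversed psmb12 (-6.97 for 88 against 60 mm and -3.99 for 88 against 65 mm), cfap52 (1.83), mns1 (2.55), ttc6 (2.31), lum (-1.02), myl13 (-0.17), mcm6 (0.6), mcm2 (0.88), mcm4 (0.9) and mcm5 (1.43), and turned the medians of the cell cycle (0.74), ribosomal (-1.43), skeletal muscle (-0.52), bone (-2.45), hox (-2.38), paraxial (-0.28) and collagen processing (-0.55) lists.

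Fits with fewer samples or other groups gave 1182 (bichir largest against the mean of the smaller sizes), 1147 (bichir 88 against 65 mm from those sizes only) and 4 (sturgeon 68 against 26 mm from those sizes only). Library size alone gave 378 for sturgeon 68 against 26 mm, and for 26 against 22 mm no filter gave 17 and the stricter filter 105. With each library left out in turn, counts ran from 4 to 796 (bichir 88 against 60 mm), 0 to 55 (65 against 60), 3 to 1098 (88 against 65), 0 to 8227 (sturgeon 68 against 22), 0 to 301 (26 against 22), 0 to 210 (68 against 26) and 206 to 699 (difference between species); lists passing ran from 6 to 11 in bichir and 3 to 8 in sturgeon. With an estimated correlation 0 lists passed in either species, and fry passed 5 in bichir (enamel, skeletal muscle, erythrocyte, immediate early, oxidative phosphorylation) and 1, leukocyte, in sturgeon. The 2 calls on list ranks became 0 with at least 1 CPM in every species, with the smallest size only, with the largest size only and with symbols of bichir and zebrafish only. The last 3 could give nothing else: the size settings leave 2 against 2 libraries (smallest p 0.333), and the last holds no sturgeon (smallest p 0.0714). The differences behind both calls kept their sign wherever they were computed. Over all lists the sign of the difference changed in 3 of 24, 3 of 27 and 5 of 27 pairs under the CPM, smallest-size and largest-size settings, in that order. Rank correlations between species moved by less than the tolerance of 0.05 under every setting but the smallest size only, which moved them to 0.621 between bichir and sturgeon and 0.566 between sturgeon and zebrafish.

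The labels number the replicates without saying that equal numbers belong together. Deviations of same-numbered libraries correlated in bichir at 0.48 (60 and 65 mm), 0.04 (60 and 88 mm) and -0.14 (65 and 88 mm). In sturgeon they correlated at -0.39 (22 and 26 mm), 0.24 (22 and 68 mm) and -0.47 (26 and 68 mm). No positive link held over all sizes of a species, but one between the 60 and 65 mm bichir libraries stays open. With the replicate block, 1049 genes passed for bichir 88 against 60 mm (711 without it) and 840 for 88 against 65 mm. It left 454 for sturgeon 68 against 22 mm, 0 for sturgeon 68 against 26 mm in edgeR, and 368 for the difference between species. The planned tests for normalised values were not run because the files hold counts. What depth limits was not tested apart from spread: simulated genes changed by 2-fold were called in 1.5% of cases in sturgeon and in 68.7% in bichir, in simulations that differed in both.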

Other observations

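The muscle score and the ranks over symbols of bichir and zebrafish only were chosen after seeing the data, and the interferon genes were noticed in the same data: the lists were written after some members had been seen, and those members were left out of the set tests.

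Antiviral genes stood higher in sturgeon scutes at 26 mm than at 22 mm, in a comparison where edgeR called 0 single genes (6459 at an unadjusted p under 0.05; DESeq2 2779). The radical SAM enzyme rsad2 (viperin) had 13 and 2.41 CPM at 22 mm, 126 and 169 at 26 mm, and 15.9 and 16.1 at 68 mm. The RNA-activated kinase eif2ak2 had 10.8 and 15.5 CPM at 22 mm and 40.2 and 73.9 at 26 mm, and ifi35 had 62.9 and 58.4 and then 169 and 158. Among genes seen first, the autophagy receptor calcoco2 had 12.7 and 12.4 CPM at 22 mm and 79.2 and 110 at 26 mm (edgeR adjusted p = 0.0531), and the RNA sensor dhx58 17.7 and 9.05 and then 97.6 and 186. Over 8 interferon response genes not seen before, 7 were higher at 26 mm, with lap3 (-0.68) the exception. The leukocyte list stood higher at 26 mm too, at a mean percentile of 68.7 and 73.5 against 57 and 56.5 at 22 mm.

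A hypothesis is that the sturgeon of 26 mm were in an interferon response. The 8 unseen genes had a median log2 change of 1.42 (quartiles 1.07 to 1.79). The directional test passed (fry adjusted p = 0.0291 over 3 tests of such lists). Camera did not with an estimated correlation (p = 0.108), and none of the 8 passed singly. The idea came from members of the same set in the same libraries, so the fry result shows that the set moved together and is no independent evidence. Fry, unlike camera, does not rank a list against the other genes. Of the 33376 tested, 6459 had an unadjusted p under 0.05 in edgeR. A single 26 mm library is argued against, since the median was 1.17 (quartiles 0.78 to 1.51) without the higher of the pair, and lay between 1.17 and 1.59 without any 22 or 26 mm library. Less muscle RNA is argued against too, with a median of 1.29 (quartiles 0.94 to 1.52) with the muscle score in the model. More leukocyte RNA at 26 mm was not tested and stays open. The leukocyte list stood at a mean percentile of 57 and 56.5 at 22 mm, 68.7 and 73.5 at 26 mm and 76 and 78.9 at 68 mm. Infection, handling and stage of the fish were not tested, since the labels give none of them but size.

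The same list was tested in bichir at 88 against 60 mm, because psmb12 and cmpk2, which rose there, respond to interferon in other vertebrates. Over 15 unseen genes 7 were higher and 8 lower (median -0.03, quartiles -0.47 to 0.7; fry adjusted p = 0.982), so a rise of the whole set was not found, and members that go both ways leave a rise of part of it open. In bichir rsad2 had 5.94 and 3.6 CPM at 60 mm and 90.1 and 10.8 at 88 mm.

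Over the 8376 symbols that bichir and zebrafish share, bone genes stood at a mean percentile of 65.8 ± 2.9 in bichir (SD, n = 6) and 49.1 ± 2.2 in zebrafish (n = 2). The 5 shared genes of the enamel list stood at 48.7 ± 3.8 and 62.9 ± 0.3. They hold no ambn, enam or scpp gene, so they do not rank the enamel matrix itself. In bichir itgb6 (41.4 against 90.4), mmp20a (20.9 against 51) and relt (73.6 against 79.4) stood lower than in zebrafish. The others, fam20a (65.3 against 62.5) and sp6 (42.3 against 31.3), stood higher. The bone and enamel list differences each had the smallest p an exact permutation test of 6 against 2 libraries can give (0.0714, adjusted 0.11), so neither passed.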
